A study of Mus musculus with 9 samples.

How the data were processed

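Gene expression was measured by RNA sequencing in 9 libraries of D3 mouse ES cells. The groups, taken from the treatment label of each sample, were VT (vector control), LAMP2A and LAMP2A+DM-αKG, with 3 libraries each. Per the labels, RNA was made into libraries with a stranded Illumina TruSeq mRNA kit, and DM-αKG was given at 4 mM for 72 h. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values measure only the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom over genes ran from 1.18 to 6.27 between them, so none were merged. This does not show that they were separate cultures.

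The authors deposited raw counts of reads per gene symbol, whole numbers that were not normalized. STAR 2.7.1 and HTSeq 0.11.2 with the mouse build mm10 are named in the submitters' processing notes; the annotation and the strand setting are not given in the sources used here, so genes that overlap another gene, antisense genes and close paralogs are less certain. The authors also deposited tables of their own comparisons, LAMP2A against VT and LAMP2A+DM-αKG against LAMP2A, made with DESeq2 per the submitters' processing notes, with no version given. Per the file headers these hold a mean signal over libraries (normalized counts), log2 fold changes with standard errors, a test score for each gene, and a p-value with its adjusted form. The deposited p-value and signal columns were used only to count calls and to compare with the fit made here. The mean signal recomputed from the counts with DESeq2 size factors lay within 0.0297% of the deposited one, and the lowest count sum of a listed gene was 10.

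The count table lists 24421 genes. Totals ran from 23636074 to 32809875 counts per library, the 10 most counted genes took 3.84 to 4.30% of them, and TMM scaling factors lay between 0.989 and 1.01. The filterByExpr function of edgeR kept 14513 genes. Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM factors, estimateDisp, glmQLFit with robust estimation, glmQLFTest), using all 9 libraries in one model of group means with 6 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 2.74%, so that small changes passed as well, and counts at a minimum of 2-fold are given beside the totals. Levels are CPM, counts scaled to the library total and its TMM factor, given as mean ± SD over 3 libraries. SE is an approximate standard error, the absolute log2 fold change over the square root of the F statistic of its test. It comes out too small where a group has few counts, so it is left out for some such genes. For correlations and principal components, log2 CPM were made with a prior count of 1. A fold against a group without a count was taken against a floor of 3 counts over the group and written as a lower bound. With 1 to 3 counts the ratio is given with a 95% counting interval. Intervals and floors cover counting error only.

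A total of 28 gene lists were written down beforehand, and 26 had at least 4 tested members. They covered core, naive, and formative and primed pluripotency, neural ectoderm, mesoderm, endoderm, trophectoderm, germline genes repressed by DNA methylation, imprinted genes, chromatin enzymes, the TCA cycle and 2-oxoglutarate metabolism, glycolysis, targets of hypoxia-inducible factor, ATF4, NRF2 and p53, cholesterol synthesis, lysosome and autophagy, chaperone-mediated autophagy machinery and cytosolic chaperones, cell cycle and proliferation, targets of LIF-STAT3, FGF-ERK, WNT-beta-catenin and TGF-beta, Nodal and BMP signalling, interferon response, and fibroblast and feeder cells. The list of mitochondrially encoded genes was not analysed here, and the 2-cell-like list is given only as counts. Of 568 list genes, 15 were not matched and 1 was matched through an older symbol. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which does not compare a list with other genes, served as alternatives. Some genes are members of more than 1 list.

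Genes were named by a rule: Lamp2, Pou5f1, Sox2 and Nanog; the 10 highest and 10 lowest log2 fold changes among genes that passed, had a mean of at least 5 CPM over the 6 libraries compared and showed no overlap between the groups (the 2 groups of 3 do not overlap in 10% of cases by chance), leaving out predicted and clone symbols; up to 4 members of each list with the smallest p; and the 8 genes with the largest opposite changes in both comparisons. Against VT, the 3 largest changes in each direction of LAMP2A+DM-αKG were named, besides genes named elsewhere. The lists, the rule, the tests of genes and lists and most alternatives were chosen before the data were examined. Members named because few of their list moved against the rest, or did not pass, were chosen after their values were seen. Some genes that met the rule are not reported by name. Coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly of mm10.

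The fit was tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 planted genes. For LAMP2A against VT it recovered 74%, 98%, 96% and 100% of genes planted at 1.2-fold, 1.5-fold, 2-fold and 4-fold, and 15 of 199 calls were unchanged genes. For LAMP2A+DM-αKG against LAMP2A it recovered 70%, 96%, 100% and 100%, with 7 unchanged genes among 190 calls. Only 200 of 14513 genes were planted, whereas 85.1% and 83.2% passed in the real comparisons. These rates may therefore not carry over to them. A list planted at 1.5-fold passed camera and 0 of 25 other lists did. The simulated genes were drawn independently of one another, so this does not show how camera behaves with correlated list members. Since both main comparisons share the LAMP2A libraries, 20 series of unchanged groups were simulated to show what the sharing gives from noise between libraries alone. Alternatives were the DESeq2 1.42.0 Wald test, limma-voom, other scaling factors (RLE, upper quartile), no filter or a minimum mean of 5 CPM, only the 6 libraries compared, the replicate number as a block, each library left out in turn, stricter thresholds, and glmTreat in edgeR against a fold change of 2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.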

Results

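RNA was sequenced from D3 cells, a line of mouse embryonic stem (ES) cells, grown without feeder cells on gelatin in medium with serum and leukemia inhibitory factor. The series holds 9 libraries in 3 groups of 3: cells carrying the empty vector (VT), cells overexpressing LAMP2A, and LAMP2A cells given 4 mM DM-αKG for 72 h. LAMP2A is the splice form of the lysosomal membrane protein LAMP2 that takes up substrates in chaperone-mediated autophagy. DM-αKG is dimethyl α-ketoglutarate, an ester of the metabolite α-ketoglutarate (2-oxoglutarate) that enters cells. The libraries held 24420412, 27351755 and 26985182 counted reads in VT, 32809875, 32172277 and 26746466 in LAMP2A, and 23636074, 25890740 and 29935663 in LAMP2A+DM-αKG. The 3 libraries of a group lay close together, with Pearson correlations of log2 CPM across genes of 0.994 to 0.997. Between groups the correlations were 0.869 to 0.872 for VT with LAMP2A, 0.887 to 0.891 for LAMP2A with LAMP2A+DM-αKG, and 0.982 to 0.984 for VT with LAMP2A+DM-αKG. The leading principal component held 87.9% of the variance, with group means of -68.5 in VT, 118.4 in LAMP2A and -49.9 in LAMP2A+DM-αKG. The next held 7.24%, with means of -27.9, -3.10 and 31.0, and set VT and LAMP2A+DM-αKG furthest apart.

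The first comparison asked how the transcriptome of ES cells changed with LAMP2A overexpression. Lamp2 (mm10 chromosome X, 38399647–38456460) rose 6.95-fold, from 58.2 ± 1.64 CPM in VT to 404 ± 2.24 CPM in LAMP2A (SD, n = 3; log2 fold change 2.80, SE 0.033). Single libraries had 56.9 to 60.0 CPM of Lamp2 in VT, 403 to 407 in LAMP2A and 95.4 to 99.3 in LAMP2A+DM-αKG. The pluripotency factors fell. Pou5f1, which encodes OCT4 (chromosome 17, 35506032–35510777), went from 1386 ± 89.0 to 323 ± 4.65 CPM, a 4.29-fold fall (log2 fold change -2.10, SE 0.035). Nanog (chromosome 6, 122707489–122714633) fell 3.71-fold (log2 fold change -1.89, SE 0.030) and Sox2 (chromosome 3, 34649995–34652461) 1.86-fold (log2 fold change -0.90, SE 0.030). Other single genes rose: Tagln, an actin-binding protein of smooth muscle, rose from 1.19 ± 0.327 to 1404 ± 15.6 CPM, and the growth factor gene Igf2 from 0.710 ± 0.256 to 1762 ± 15.7 CPM. Counts per gene do not separate the LAMP2A splice form from the other forms of Lamp2, nor the introduced copy from the endogenous gene.

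**Figure D1:**
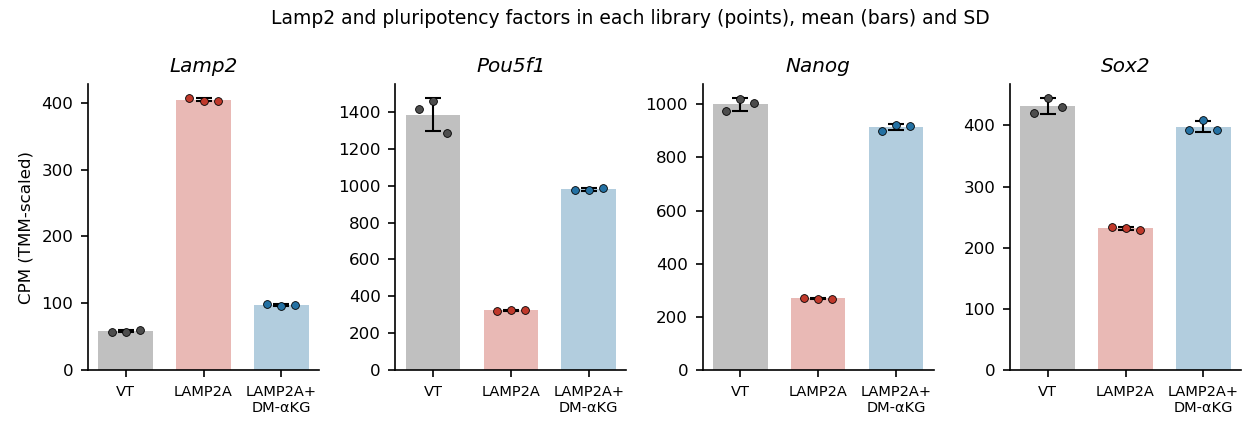
CPM (TMM-scaled, linear axes from 0) of Lamp2, Pou5f1, Nanog and Sox2 in each library (points), with the mean (bars) and SD (error bars) of the 3 libraries of VT, LAMP2A and LAMP2A+DM-αKG. Lamp2 averaged 58.2, 404 and 97.2 CPM in the 3 groups, and Nanog 999.9, 269.6 and 914 CPM.

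The genes with the highest fold changes in LAMP2A were barely counted in VT. Acta2, smooth muscle actin, reached 486 ± 6.14 CPM in LAMP2A against 3 counts in the 3 VT libraries together, a ratio of 12651 with a 95% counting interval of 4329 to 61349.8. No read of Hoxb2, Ccdc80, C1qtnf3 or Actc1 was counted in VT. Against a floor of 3 counts over the group they were at least 928-fold, 839.8-fold, 788-fold and 528-fold higher in LAMP2A. Tnc, which encodes the matrix protein tenascin C, rose from 0.0769 ± 0.0376 to 281 CPM (log2 fold change 11.76). The collagen gene Col12a1, the protease gene Prss23 and the guanylate-binding protein gene Gbp2 had 2, 2 and 1 counts in VT, with ratios of 3918 (1084 to 32358), 3764 (1042 to 31084) and 3899 (699.5 to 154048). At the other end were Kirrel2 and Nphs1, neighbouring genes for cell adhesion proteins of the podocyte slit diaphragm. They fell from 37.8 to 0.264 ± 0.0451 CPM (log2 fold change -7.15) and from 60.9 to 0.534 ± 0.144 CPM (log2 fold change -6.82). Inhbb, an inhibin and activin subunit, and Khdc3, part of the maternal subcortical complex, fell 51.6-fold and 38.3-fold. The next lowest were Nkx6-3, Ppp1r14d, Myo1f, Pou2f3, Accsl and Slc52a3, which fell 28.9-fold to 18.0-fold.

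All 17 measured genes of naive pluripotency fell in LAMP2A, with a median log2 fold change of -2.11 (camera adjusted p = 1.0e-10, adjusted p = 0.00768 with an estimated correlation). Tcl1 fell 15.2-fold, Nr0b1 6.86-fold, the nuclear receptor gene Esrrb 5.88-fold and the transcription factor gene Klf4 5.83-fold. The core pluripotency list had 12 of 14 members lower (camera adjusted p = 1.8e-05, adjusted p = 0.0731 with an estimated correlation), among them Tdgf1, a Nodal co-receptor, at 8.49-fold, Fgf4 at 4.11-fold and L1td1 at 3.83-fold. Its 2 higher members were Lin28a and Trim71, regulators of RNA that also act in later development (log2 fold changes 0.94 and 0.26). Of 15 targets of LIF and STAT3, 12 fell and 3 rose (camera adjusted p = 5.2e-04, adjusted p = 0.0716 with an estimated correlation). Socs3, the feedback inhibitor of that pathway, fell 7.79-fold, while Junb and the receptor genes Lifr and Il6st were higher. Formative and primed pluripotency genes went the other way, with 14 of 18 higher and 3 lower (camera adjusted p = 0.00489, adjusted p = 0.0716 with an estimated correlation). Cdh2, N-cadherin, rose 38.2-fold, Sox4 19.6-fold and Sall2 10.7-fold, while Zic5, Tcf15 and Foxd3 fell.

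Endoderm genes were higher in 21 of 22 cases (median log2 fold change 3.10; camera adjusted p = 1.1e-07, adjusted p = 0.0159 with an estimated correlation), with the basement membrane genes Col4a2 and Lamb1 up 8.72-fold and 8.56-fold and the receptor gene Cubn up 24.4-fold; Sox7 fell. Mesoderm genes were higher in 15 of 19 (camera adjusted p = 6.1e-04, adjusted p = 0.0716 with an estimated correlation), including the transcription factor genes Hand1 at 200.2-fold and Twist1 at 13.1-fold and the receptor gene Pdgfra at 6.40-fold, and Mesp2 was the single lower member. Trophectoderm genes rose in 14 of 16 (camera adjusted p = 6.1e-04, adjusted p = 0.0731 with an estimated correlation), led by the keratin genes Krt18 (56.9-fold), Krt19 (33.6-fold) and Krt8 (16.7-fold); Cdx1 and Ets2 fell. Neural ectoderm genes were mixed, with 10 higher and 4 lower of 14 (camera adjusted p = 0.112): Crabp2 rose 37.0-fold and Nes 5.59-fold, whereas Stmn2 fell 2.60-fold, with Tubb3, Map2 and Neurod1 also lower. Of fibroblast and feeder cell markers, 15 of 17 were higher (median 5.63; camera adjusted p = 6.6e-05, adjusted p = 0.0716 with an estimated correlation). Col1a1 rose from 0.968 to 59.2 CPM and Col5a1 from 28.6 to 156 CPM, while Thy1 and Cd34 fell.

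Targets of several signalling pathways changed as well. Of 17 TGF-beta, Nodal and BMP targets 13 rose and 3 fell (camera adjusted p = 5.2e-04, adjusted p = 0.0731 with an estimated correlation). Cyr61, Id2, Id3 and Ctgf rose 31.9-fold, 24.9-fold, 11.6-fold and 9.11-fold, and Nodal itself, Smad7 and Pmepa1 fell. WNT-beta-catenin targets were higher in 14 of 16 (camera adjusted p = 0.00458, adjusted p = 0.0716 with an estimated correlation), among them Dkk1, an inhibitor of WNT signalling, at 132-fold and Ccnd2 at 24.5-fold; Cdx1 and Notum fell. Targets of FGF and ERK split, with 8 higher and 7 lower of 16 (camera adjusted p = 0.754): Phlda1 and Dusp5 rose 9.89-fold and 9.23-fold, and Etv4 and Spry4 fell 13.0-fold and 6.08-fold.

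Metabolic and proliferation genes shifted by smaller amounts. Genes of the TCA cycle and of 2-oxoglutarate metabolism were lower in 24 of 29 cases (median -0.41; camera adjusted p = 4.4e-05, adjusted p = 0.0731 with an estimated correlation). Got1, which converts 2-oxoglutarate and aspartate into glutamate and oxaloacetate, fell 2.16-fold, the isocitrate dehydrogenase subunit gene Idh3a 1.98-fold and the pyruvate carboxylase gene Pcx 2.28-fold. Aco1, Idh2 and Dlst rose slightly (log2 fold changes 0.07, 0.16 and 0.09). Glycolysis genes were lower in 13 of 19 and higher in 6 (camera adjusted p = 0.0445, adjusted p = 0.577 with an estimated correlation): the hexokinase gene Hk2 fell 2.44-fold and Pfkp 3.07-fold, while the glucose transporter gene Slc2a1 rose 1.94-fold. Targets of ATF4 in the amino acid response fell in 18 of 26 (camera adjusted p = 0.00474, adjusted p = 0.225 with an estimated correlation), including Slc7a3 at 3.24-fold and Shmt2 at 2.37-fold. NRF2 targets (3 higher, 9 lower of 17, the higher ones being Gclc, Me1 and Slc7a11; camera adjusted p = 0.0654) and targets of hypoxia-inducible factor (10 higher, 6 lower of 20; camera adjusted p = 0.402) did not pass as lists. Cell cycle genes were lower in 20 of 24 (camera adjusted p = 1.8e-05, adjusted p = 0.0181 with an estimated correlation), Ccne1 by 2.53-fold and Rrm2 by 1.93-fold, with Ccnd1 and Myc higher. Among p53 targets 13 rose and 6 fell of 20 (camera adjusted p = 0.0824), and the cell cycle inhibitor gene Cdkn1a rose 3.18-fold.

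The lysosome and autophagy list, which leaves out Lamp2, had 20 of 30 members higher and 6 lower (camera adjusted p = 0.00227, adjusted p = 0.143 with an estimated correlation). Cd63 rose 2.94-fold, the cathepsin gene Ctsl 2.60-fold and Sqstm1 2.34-fold, whereas Tfeb, a transcription factor of lysosomal genes, fell 6.18-fold. In the list of chaperone-mediated autophagy machinery and cytosolic chaperones, Lamp2 was the single member that rose, and 12 of 16 fell (camera adjusted p = 0.00339, adjusted p = 0.111 with an estimated correlation). The lower members were mostly chaperones, including Hsp90aa1 at 2.13-fold and Hsph1, which went from 238 to 143 CPM.

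In all, 12355 of the 14513 genes tested (85.1%) passed the adjusted p threshold in edgeR's quasi-likelihood test, 6240 higher and 6115 lower in LAMP2A. At least 2-fold changes were less even, with 2877 genes higher and 1394 lower. The authors' deposited table lists 16283 genes and calls 6328 higher and 5847 lower, and the 11641 genes called in both had the same sign. Adjusted over the list alone, the counts of list members were equal to those over all genes except for p53 targets, where 7 in place of 6 fell. Of 26 lists, 19 passed camera with its preset correlation and 3 with an estimated one (naive pluripotency, endoderm and cell cycle). Among genes with a mean of at least 5 CPM the call was lost for glycolysis (adjusted p = 0.0973; 8.4e-05 to 0.577 over its alternatives) and for WNT-beta-catenin targets (adjusted p = 0.0582; 2.7e-09 to 0.0716 over its alternatives), and without VT replicate 1 that of glycolysis was lost too (adjusted p = 0.0546), while without VT replicate 3 NRF2 targets passed (adjusted p = 0.0478; 9.2e-08 to 0.189 over its alternatives).

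The second comparison asked what DM-αKG changed in cells overexpressing LAMP2A. Pluripotency factors were higher with DM-αKG: Pou5f1 rose 3.03-fold, from 323 ± 4.65 to 980.2 ± 7.27 CPM (SD, n = 3; log2 fold change 1.60, SE 0.035), Nanog 3.39-fold to 914 ± 12.3 CPM (log2 fold change 1.76, SE 0.030) and Sox2 1.72-fold to 398 ± 9.51 CPM (log2 fold change 0.78, SE 0.030). Tagln fell from 1404 to 0.853 ± 0.181 CPM (log2 fold change -10.70) and Tnc from 281 to 0.134 ± 0.178 CPM (log2 fold change -11.08). Lamp2 itself also fell, 4.16-fold, from 404 ± 2.24 to 97.2 ± 2.00 CPM (log2 fold change -2.06, SE 0.031). The libraries given DM-αKG carried Lamp2 at 1.67-fold the VT level.

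Among the most lowered genes, Acta2 kept 3 counts over the 3 libraries, against 486 CPM without DM-αKG, a ratio of 12904 (95% counting interval 4415 to 62574). C1qtnf3, Hoxb2 and Ccdc80 had 1, 2 and 3 counts left, with ratios of 2412 (432 to 95289), 1420.4 (393 to 11734) and 857 (293 to 4156). Cyp1b1, Acta1, Col12a1 and Prss23 fell from 68.4, 313, 100.2 and 96.2 CPM to 0.0561, 0.323, 0.107 and 0.132 CPM. Kirrel2 and Nphs1 rose 77.2-fold and 69.7-fold, Inhbb 38.1-fold and Nkx6-3 18.6-fold. Grin1, a subunit of the NMDA glutamate receptor, rose from 1.14 ± 0.144 to 48.8 CPM (log2 fold change 5.41). The transcription factor genes Foxn4 and Pou2f3 rose 42.4-fold and 25.5-fold, the protease inhibitor gene A2m 33.1-fold, Ly6g6e 28.9-fold and Igsf21 by a log2 fold change of 4.58.

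All 17 measured genes of naive pluripotency rose with DM-αKG (median log2 fold change 1.88; camera adjusted p = 1.5e-10, adjusted p = 0.00799 with an estimated correlation), Tcl1 by 10.6-fold, Jam2 by 6.98-fold and Klf4 by 6.11-fold. The core list had 12 of 14 members higher, Tdgf1 at 8.49-fold, and Lin28a and Trim71 lower (camera adjusted p = 4.3e-05, adjusted p = 0.0708 with an estimated correlation). Targets of LIF and STAT3 rose in 10 of 15, Socs3 by 8.16-fold, and fell in 3, which were Junb, Lifr and Il6st (camera adjusted p = 0.00289, adjusted p = 0.0575 with an estimated correlation). Formative and primed genes were lower in 15 of 18 (camera adjusted p = 9.7e-04, adjusted p = 0.0277 with an estimated correlation): Cdh2 fell 22.4-fold, Sox4 13.5-fold and the DNA methyltransferase gene Dnmt3a 3.66-fold, whereas Zic5, Tcf15 and Foxd3 rose.

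With DM-αKG endoderm genes were lower in 21 of 22 (median -2.62; camera adjusted p = 1.5e-07, adjusted p = 0.0167 with an estimated correlation), Cubn by 33.4-fold and Dab2 by 18.0-fold, with Sox7 higher. Mesoderm genes were lower in 14 of 19 (median -2.77; camera adjusted p = 5.8e-04, adjusted p = 0.0474 with an estimated correlation), Hand1 by 157-fold and Gata2 by 10.5-fold, with Eomes and Mesp2 higher. Trophectoderm genes were lower in 12 of 16 (camera adjusted p = 0.00150, adjusted p = 0.0708 with an estimated correlation), with Krt18 at 38.5-fold and Gata3 at 58.0-fold, and higher in 3, namely Ascl2, Cdx1 and Ets2. Neural ectoderm genes remained divided, 5 higher and 9 lower of 14 (camera adjusted p = 0.155), with Crabp2 lower by 48.8-fold and Stmn2 and Tubb3 higher by 1.89-fold and 1.93-fold, beside Map2, Neurod1 and Sox21. The fibroblast and feeder cell markers fell in 16 of 17 cases (median -3.78; camera adjusted p = 1.6e-05, adjusted p = 0.0325 with an estimated correlation), Col1a1 by 61.0-fold; Cd34 rose. TGF-beta, Nodal and BMP targets fell in 14 of 17 (camera adjusted p = 7.3e-05, adjusted p = 0.0474 with an estimated correlation), Id3 by 14.6-fold, while Nodal, Smad7 and Pmepa1 rose. WNT-beta-catenin targets fell in 13 of 16 (camera adjusted p = 3.0e-04, adjusted p = 0.0277 with an estimated correlation), Dkk1 by 155-fold, and Cdx1 rose. Targets of FGF and ERK again split, 4 higher and 9 lower of 16 (camera adjusted p = 0.142), with Etv4 higher by 8.88-fold along with Spry4, Etv1 and Etv5, and Phlda1 lower by 9.96-fold.

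Metabolic lists rose with DM-αKG. Of 29 genes of the TCA cycle and of 2-oxoglutarate metabolism 27 were higher (median 0.47; camera adjusted p = 2.2e-07, adjusted p = 0.0351 with an estimated correlation), the alanine aminotransferase gene Gpt2 by 2.39-fold and Got1 by 2.29-fold; Dlst fell slightly (log2 fold change -0.08). Glycolysis genes rose in 16 of 19 (camera adjusted p = 5.2e-06, adjusted p = 0.190 with an estimated correlation), Pfkp by 4.05-fold, Hk1 by 3.14-fold and Pgk1 by 2.50-fold, and Pfkm and Eno2 fell. Targets of hypoxia-inducible factor rose in 13 of 20 and fell in 4 (camera adjusted p = 9.7e-04, adjusted p = 0.0277 with an estimated correlation), Bhlhe40 rising 3.49-fold and Ak4 3.06-fold, and P4ha1, Adm, Car12 and Ddit4 falling. ATF4 targets rose in 21 of 26 (camera adjusted p = 1.0e-06, adjusted p = 0.0580 with an estimated correlation), among them Trib3 at 3.88-fold and the serine and folate pathway genes Shmt2, Mthfd2 and Psat1 at 3.31-fold, 3.22-fold and 2.45-fold; Atf3 and Cebpb fell. NRF2 targets rose in 16 of 17 (camera adjusted p = 2.0e-05, adjusted p = 0.0277 with an estimated correlation), Nqo1 by 2.60-fold and the glutathione reductase gene Gsr by 2.28-fold. Cell cycle genes rose in 20 of 24 (camera adjusted p = 2.0e-05, adjusted p = 0.0209 with an estimated correlation), Ccnd3 by 1.96-fold, while Myc fell 3.64-fold and Ccnd1 was lower too. p53 targets fell in 15 of 20 (camera adjusted p = 0.00835, adjusted p = 0.0474 with an estimated correlation), Plk2 by 3.47-fold and Cdkn1a by 2.44-fold, with Bax, Gdf15 and Rps27l higher. Lysosome and autophagy genes fell in 24 of 30 (camera adjusted p = 7.5e-04, adjusted p = 0.112 with an estimated correlation), Cd63 by 2.86-fold, and Tfeb rose 3.77-fold, along with others such as Gla, Atp6v1h and Wipi1. Chaperones rose in 12 of 16 members of their list (camera adjusted p = 0.00835, adjusted p = 0.125 with an estimated correlation), Hsp90aa1 by 2.17-fold, while Lamp2 and Ctsa fell.

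By edgeR's quasi-likelihood test 12081 of 14513 genes (83.2%) passed, 5967 higher and 6114 lower with DM-αKG. At least 2-fold changes numbered 1170 higher and 2553 lower. The authors' deposited table for this comparison lists 16289 genes and calls 5821 higher and 6219 lower, and the 11509 genes called in both had the same sign. Adjusted over the list alone, 22 in place of 21 ATF4 targets rose, and the other list counts were equal. Of 26 lists, 22 passed camera with the preset correlation and 15 with an estimated one. Among genes with a mean of at least 5 CPM the chaperone list no longer passed (adjusted p = 0.0621; 1.1e-05 to 0.125 over its alternatives).

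**Figure D2:**
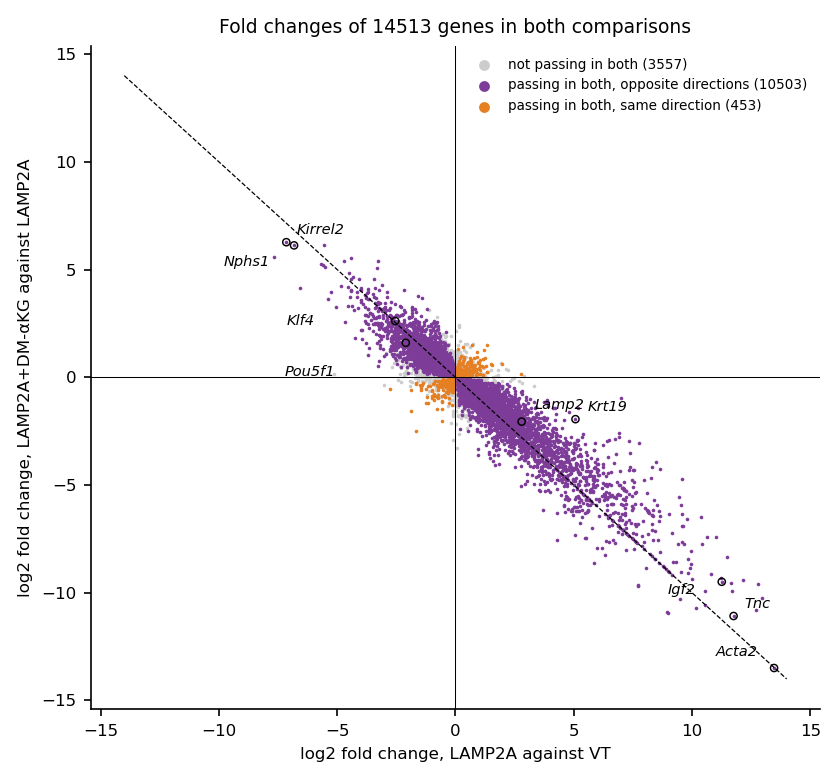
Fitted log2 fold change of each of the 14513 genes tested in LAMP2A against VT (x axis) and in LAMP2A+DM-αKG against LAMP2A (y axis). Each point is a gene, coloured by whether it passed in both comparisons and in which directions, and the dashed line marks equal and opposite changes; 10503 genes passed in opposite directions and 453 in the same direction.

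The series also asks how far the changes of LAMP2A cells were absent when DM-αKG was given. No library was taken from the treated cells before DM-αKG, so whether they had first carried these changes is not known. Acta2, Acta1, Tagln, Tnc, Col12a1, C1qtnf3, Ccdc80 and Hoxb2 had the largest opposite changes. Each passed as higher in LAMP2A than in VT and as lower with DM-αKG than without. Of the 6240 genes higher in LAMP2A, 5389 (86.4%) fell with DM-αKG, 246 rose further and 605 did not pass. Of the 6115 lower genes, 5114 (83.6%) rose, 207 fell further and 794 did not pass. Unrelated lists of these sizes would share 2629 and 2514 genes in opposite directions. Among genes raised at least 2-fold, 2778 of 2877 (96.6%) fell, and the median log2 fold change against VT went from 2.10 without DM-αKG to 0.34 with it. Among those lowered at least 2-fold, 1248 of 1394 (89.5%) rose, and the median went from -1.57 to -0.33. Both comparisons use the same LAMP2A libraries, which by itself makes opposite changes: in 20 simulated series with unchanged groups at most 1 gene was called in opposite directions, the correlation of the log2 fold changes across genes had a median of -0.464 and their covariance one of -0.00874. The observed correlation was -0.940 and the covariance -2.33, a difference of covariances of -2.32. The small simulated covariance argues against noise between the shared libraries as the main cause of the opposite changes. A trait common to the 3 LAMP2A libraries would enter both comparisons with opposite sign, whatever its origin, and the simulation could not address it. Part of the excess in overlap may also come from the shared libraries, because the simulated groups held no real changes. At 3 per group these libraries are too few to give each comparison 2 of its own.

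The LAMP2A+DM-αKG libraries were also compared with VT. Of the genes changed in LAMP2A, 2726 higher and 2981 lower ones were still on that side of VT with DM-αKG, 2684 and 2136 did not pass, and 830 and 998 lay past VT. Lamp2 was 1.67-fold higher at 97.2 ± 2.00 against 58.2 ± 1.64 CPM (SD, n = 3; log2 fold change 0.74, SE 0.035), and Pou5f1 1.41-fold lower (log2 fold change -0.50, SE 0.033). Nanog and Sox2 were lower by 1.09-fold and 1.08-fold (log2 fold change -0.13, SE 0.028, and log2 fold change -0.12, SE 0.029). The keratin gene Krt19 was higher by 8.75-fold (log2 fold change 3.13, SE 0.093), the heparanase gene Hpse 7.71-fold (log2 fold change 2.95, SE 0.12) and Ndufa4l2, a mitochondrial gene induced in hypoxia, 4.82-fold (log2 fold change 2.27, SE 0.049). Accsl, Spata31d1b and Smyd1 were lowest, at 5.23-fold, 4.99-fold and 4.64-fold below VT. Ndufa4l2 and Smyd1 were not left over from LAMP2A, where they had gone the other way (log2 fold changes -1.42 and 0.19 against VT).

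Targets of hypoxia-inducible factor stood above VT in 17 of 20 cases (median 1.07; camera adjusted p = 8.6e-13, adjusted p = 0.00466 with an estimated correlation). P4ha2, a collagen prolyl hydroxylase gene, was 3.37-fold higher, the mitophagy gene Bnip3 2.67-fold, Ddit4 2.40-fold and Bhlhe40 2.12-fold above VT, while Pdk1, Car9 and Pfkfb4 did not pass (log2 fold changes -0.02, -0.61 and 0.14). Several were already raised without DM-αKG: P4ha2 had 53.1 CPM in LAMP2A and 54.6 with DM-αKG, Ddit4 113 and 88.5, and P4ha1, Adm and Car12 were also higher in LAMP2A. Glycolysis genes were higher in 16 of 19 (camera adjusted p = 5.1e-13, adjusted p = 0.119 with an estimated correlation), Pfkfb3 by 2.42-fold, Hk1 by 2.21-fold, Slc2a1 by 2.19-fold and Pgk1 by 1.79-fold. Pfkfb3 and Slc2a1 were already raised without DM-αKG. Pfkfb3 had 116 CPM in LAMP2A and 124 with DM-αKG, and Slc2a1 1205 and 1360. Hk1 and Pgk1 were lower in LAMP2A than in VT. ATF4 targets were higher in 21 of 26 and lower in 4 (camera adjusted p = 5.9e-07, adjusted p = 0.114 with an estimated correlation), Trib3 by 1.47-fold, with Slc7a3, Cth, Chac1 and Sesn2 lower. NRF2 targets were higher in 14 of 17 (camera adjusted p = 5.1e-05, adjusted p = 0.0604 with an estimated correlation), Gsr by 1.44-fold, and Prdx1 and Taldo1 were lower. Genes of the TCA cycle and of 2-oxoglutarate metabolism had 11 higher and 3 lower of 29 (camera adjusted p = 0.0970), Gpt2 being 1.49-fold higher and Suclg1, Sdhb and Pcx lower.

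**Figure D3:**
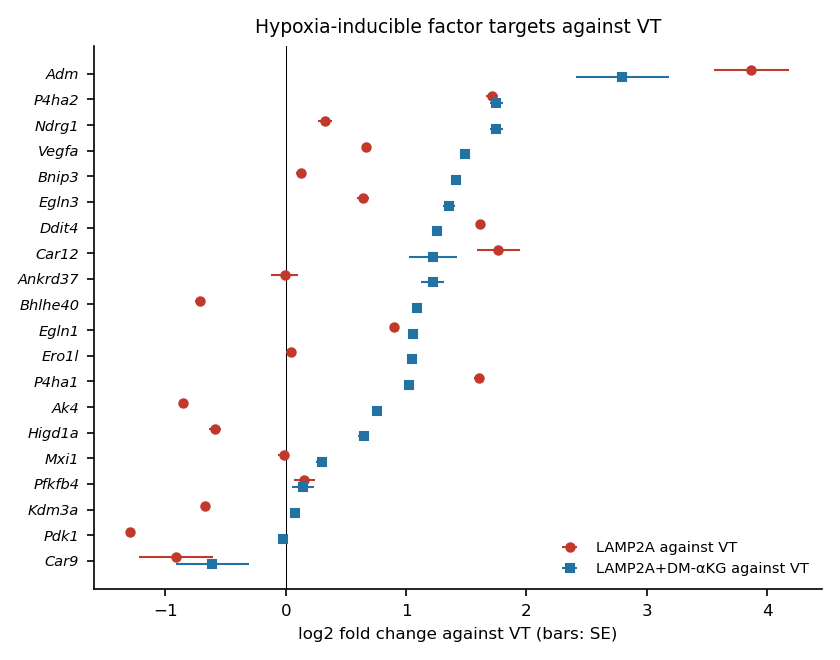
Log2 fold change against VT (x axis; error bars are SE) of the 20 measured targets of hypoxia-inducible factor (rows) in LAMP2A (circles) and in LAMP2A+DM-αKG (squares), 3 libraries per group. The list median was 0.14 in LAMP2A and 1.07 in LAMP2A+DM-αKG. The SE may be too small for members with few counts, such as Adm at 0.115 CPM in VT.

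Pluripotency genes were mostly below VT. Of the naive genes 15 were lower and 2 higher of 17 (median -0.32; camera adjusted p = 5.9e-07, adjusted p = 0.0151 with an estimated correlation), Nr0b1 by 1.55-fold and Esrrb by 1.26-fold, and Jam2 and Klf4 were the higher ones. Klf4 was only 1.05-fold higher (edgeR adjusted p = 0.0492; 0.00515 to 0.183 over 17 alternatives that test against no change), a call lost in 13 of them, including those without VT replicate 1, any LAMP2A library or any LAMP2A+DM-αKG library. Core genes were lower in 12 of 14 (camera adjusted p = 1.1e-05, adjusted p = 0.114 with an estimated correlation), Lin28a, which had risen in LAMP2A, by 2.20-fold and L1td1 by 1.65-fold, and Fgf4 was higher. Cell cycle genes were lower in 15 of 24 (camera adjusted p = 0.00403, adjusted p = 0.0604 with an estimated correlation), Myc by 2.16-fold, with Aurkb, Bub1 and E2f1 higher. FGF and ERK targets were lower in 8 of 16 (camera adjusted p = 0.00471, adjusted p = 0.114 with an estimated correlation), Spry4 by 1.60-fold and Etv4 by 1.47-fold, and higher in 3, which were Spry1, Fos and Ier3. Endoderm genes were higher in 13 of 22 (median 0.57, or 0.56 with the member that had no count in a group set at its floor; camera adjusted p = 3.5e-04, adjusted p = 0.0604 with an estimated correlation), Col4a2 by 2.24-fold and Col4a1 by 2.14-fold, with Amn and Cubn lower. Trophectoderm genes were higher in 9 of 16 and lower in 2, Cdx2 and Ets2 (median 0.29, or 0.45 at that floor; camera adjusted p = 0.0349, adjusted p = 0.236 with an estimated correlation), a call lost without VT replicate 1 (adjusted p = 0.0571) or VT replicate 3 (adjusted p = 0.0637; 2.8e-05 to 0.236 over its alternatives).

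The other lists described above did not pass against VT. Mesoderm genes were higher in 6 and lower in 4 of 19 (camera adjusted p = 0.346), the lower ones being Mesp2, Kdr, Bmp4 and Gata2. Fibroblast and feeder cell markers were higher in 4 (Col5a1, Vim, Fbn1 and Mmp2) and lower in 2 (Thy1 and Tagln) of 17 (adjusted p = 0.282), the call of Tagln being lost in 7 of 17 alternatives (edgeR adjusted p = 0.0418; 0.00821 to 0.254 over them), including those without replicate 2 or 3 of VT or of LAMP2A+DM-αKG. Col1a1 stood at 0.990 ± 0.418 CPM against 0.968 ± 0.160 CPM. TGF-beta, Nodal and BMP targets were higher in 9 and lower in 5 of 17, with Lefty1, Lefty2, Smad7 and Id3 among the lower ones (adjusted p = 0.239). Formative and primed genes were higher in 6 and lower in 8 of 18 (adjusted p = 0.346; median 0.02, mean -0.09, opposite in sign). Neural ectoderm genes were higher in 3 (Tubb3 and Sox21 among them) and lower in 4 (Sox1, Neurod1, Stmn2 and Crabp2) of 14 (adjusted p = 0.973), the call of Crabp2 being lost in 3 of 17 alternatives (edgeR adjusted p = 0.0233; 0.0176 to 0.175 over them), those without VT replicate 2 or LAMP2A+DM-αKG replicate 1 or 3. WNT-beta-catenin targets had 3 higher (Lef1, Nkd1 and Lgr5) and 5 lower (Tcf7, Notum, Cdx2, Ccnd1 and Ccnd2) of 16 (adjusted p = 0.372; median -0.03, mean 0.20, opposite in sign), and LIF and STAT3 targets had 3 higher (Klf4 and Il6st among them) and 7 lower of 15 (adjusted p = 0.0778). Lysosome and autophagy genes had 12 higher and 9 lower of 30 (adjusted p = 0.429), the chaperone list 3 (Lamp2, Hspa1a and Bag1) and 8 of 16 (adjusted p = 0.164) and p53 targets 5 (Cdkn1a, Pmaip1, Gdf15, Perp and Polk) and 9 of 20 (adjusted p = 0.346).

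In edgeR's quasi-likelihood test 8517 of 14513 genes (58.7%) passed between LAMP2A+DM-αKG and VT, 4258 higher and 4259 lower, of which 570 and 381 changed at least 2-fold. Adjusted over the list alone, the counts of lower members changed by 1 for glycolysis (1 in place of 0), cell cycle (16 in place of 15) and fibroblast markers (1 in place of 2) among the lists above. Of 26 lists, 11 passed camera with the preset correlation and 2 with an estimated one (naive pluripotency and hypoxia-inducible factor targets). WNT-beta-catenin targets passed among genes with a mean of at least 5 CPM (adjusted p = 0.0338; 3.2e-05 to 0.486 over its alternatives), and the TCA cycle list without VT replicate 2 (adjusted p = 0.0234; 4.0e-04 to 0.478 over its alternatives).

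**Figure D4:**
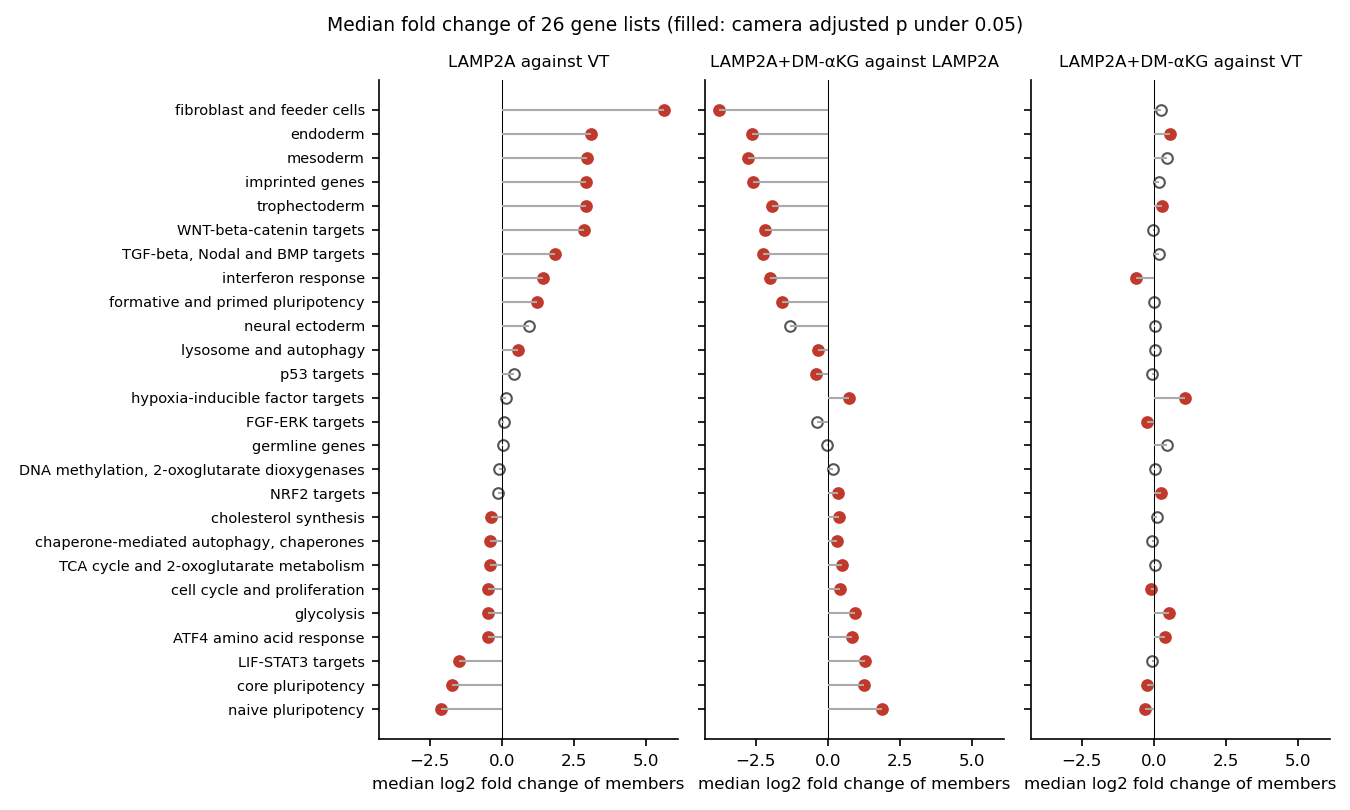
Median log2 fold change of the tested members of 26 gene lists (rows; x axis) in the 3 comparisons (panels). Filled points passed camera with its preset correlation and open points did not; naive pluripotency genes had medians of -2.11, 1.88 and -0.32.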

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

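The test against a fold change of 2 (glmTreat in edgeR) and the thresholds applied to opposite changes were chosen after seeing the data. Under glmTreat 3550 genes passed in LAMP2A against VT (2468 higher, 1082 lower), 3020 in LAMP2A+DM-αKG against LAMP2A (850 higher, 2170 lower), 308 in LAMP2A+DM-αKG against VT (160 higher, 148 lower) and 2608 in opposite directions. With an adjusted p under 0.05 and a minimum of 2-fold there were 4271 (2877 higher, 1394 lower), 3723 (1170 higher, 2553 lower), 951 (570 higher, 381 lower) and 3206. Both ask for a larger change, which by construction passes fewer genes. In the other alternatives the counts moved by less than 1.5 times, from 9386 to 13179, 9206 to 12820, 7031 to 8561 and 8052 to 11034, and the lowest and highest of them came from testing fewer or more genes. The DESeq2 Wald test gave 11894, 11538, 7598 and 10016. Leaving out 1 library at a time gave 12107 to 12440, 11750 to 12372, 7739 to 8371 and 10220 to 10641 genes. Of the gene lists, 3 in place of 19 passed in LAMP2A against VT with an estimated correlation and 2 in place of 11 in LAMP2A+DM-αKG against VT, where fry passed 24; camera compares a list with other genes, and fry asks whether its members changed at all. Without 1 library 18 to 20, 22 and 10 to 13 lists passed in the 3 comparisons. The replicate numbers of the labels did not pair the samples: deviations from the group means of libraries with the same number correlated across genes by -0.0266 to 0.0117. With the replicate number as a block 12341, 12065 and 8462 genes passed, 10487 in opposite directions, and 19, 22 and 11 lists. Of 7180 alternatives of 401 results for named genes, 6977 kept their call, 190 no longer passed, 133 of them under glmTreat, 13 newly passed and 0 changed direction; outside glmTreat these were all in LAMP2A+DM-αKG against VT, where the changes were smallest, and the cause was not tested. Scaling by RLE or upper quartile moved the median log2 fold change of all genes to between -0.02 and 0.02. Like TMM, these factors align the bulk of the genes, so medians near 0 could not reveal a shift common to most genes. Depth limits genes at a few counts per group, such as Acta2 outside LAMP2A, whose counting intervals span more than 10-fold.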

Other observations

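The tests of explanations given here, the splits of the libraries and the genes named as exceptions were chosen after the results were seen, and the lists were planned. Imprinted genes, expressed from a single parental allele, were higher in LAMP2A than in VT in 21 of 23 cases, and Phlda2 alone was lower (median log2 fold change 2.93; camera adjusted p = 1.1e-07, adjusted p = 0.0716 with an estimated correlation). Mest rose 35.0-fold from 146 to 5120.4 CPM, Peg3 37.1-fold and Peg10 13.8-fold. With DM-αKG 21 fell and Phlda2 rose (median -2.61; camera adjusted p = 1.1e-08, adjusted p = 0.0277 with an estimated correlation), with Mest at 152 CPM, Igf2 at 2.44 CPM and H19 lower by 656-fold. Against VT 12 were higher and 6 lower (camera adjusted p = 0.328). Of interferon response genes, 14 of 19 rose in LAMP2A and Zbp1 fell (camera adjusted p = 0.00539, adjusted p = 0.0731 with an estimated correlation; adjusted p = 0.215 among genes with a mean of at least 5 CPM; 8.7e-08 to 0.215 over its alternatives), Isg15 by 91.0-fold. With DM-αKG Isg15 fell 199-fold, from 10.9 ± 0.440 to 0.0502 ± 0.0444 CPM. Its VT level was 0.114 ± 0.0616 CPM, so both its folds rest on few counts. In total 17 list members fell with DM-αKG, Bst2 by 4.07-fold, and Zbp1 rose (camera adjusted p = 1.1e-04, adjusted p = 0.0277 with an estimated correlation). Against VT 7 were lower (median -0.63, or -0.50 with a member without counts at its floor; camera adjusted p = 0.0112, adjusted p = 0.114 with an estimated correlation), Ddx58 by 2.77-fold. Oasl2 was higher, a call lost when adjusted over the list alone and in 8 of 15 alternatives (edgeR adjusted p = 0.0463; 0.00212 to 0.178 over them), including those without VT replicate 2 or 3, LAMP2A replicate 2 or 3, or any LAMP2A+DM-αKG library.

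Among enzymes of DNA methylation and chromatin dioxygenases that use 2-oxoglutarate, 9 rose and 15 fell of 25 in LAMP2A (camera adjusted p = 0.129), and 14 rose and 7 fell with DM-αKG (camera adjusted p = 0.107). Tet3, a 5-methylcytosine dioxygenase, was 3.06-fold higher in LAMP2A than in VT and 2.67-fold lower with DM-αKG than without. Dnmt3a was 1.89-fold higher in LAMP2A and 3.66-fold lower with DM-αKG, at a level 1.94-fold below VT. Dnmt3l, the cofactor of the de novo methyltransferases, fell 2.35-fold in LAMP2A and stayed 2.31-fold below VT with DM-αKG. Against VT 8 were higher and 9 lower (camera adjusted p = 0.381; median 0.04, mean -0.10, opposite in sign). Germline genes repressed by DNA methylation were divided in LAMP2A, 7 higher and 7 lower of 17 (camera adjusted p = 0.780, where fry took the other direction; fry adjusted p = 0.0913), and with DM-αKG, 6 and 7 (camera adjusted p = 0.850; median -0.02, mean 0.07, opposite in sign). Tdrd1 was 6.07-fold higher in LAMP2A than in VT and 3.84-fold lower with DM-αKG than without, and Dazl rose 2.04-fold with DM-αKG. Against VT 10 were higher and 5 lower, namely Hormad1, Rpl10l, Tex19.1, Tuba3a and Zfp42 (camera adjusted p = 0.214). Cholesterol synthesis genes fell in 16 of 25 and rose in 6 in LAMP2A (camera adjusted p = 0.0297, adjusted p = 0.0839 with an estimated correlation; adjusted p = 0.0658 among genes with a mean of at least 5 CPM; 7.0e-08 to 0.0839 over its alternatives), Pmvk by 2.59-fold. With DM-αKG 19 rose, Pmvk by 2.87-fold and Insig1 by 1.99-fold, and members including Sqle, Sc5d and Mvk fell (camera adjusted p = 7.5e-04, adjusted p = 0.0277 with an estimated correlation). Against VT 15 were higher and 6 lower, or 7 lower adjusted over the list alone (camera adjusted p = 0.0770; adjusted p = 0.0372 without VT replicate 2; 3.3e-05 to 0.152 over its alternatives). The 18 genes of the 2-cell-like state in the count table had 15 counts over the VT libraries, 69 over LAMP2A and 14 over LAMP2A+DM-αKG, with 3, 23 and 1 for Zscan4d, too few to be tested.

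The LAMP2A+DM-αKG libraries lay close to VT, and Lamp2 was lower in them as well. Of the rise of Lamp2 in LAMP2A, 11.3% (SD 0.578 over 3 libraries) was kept with DM-αKG, against a median of 4.81% over the other 2876 genes raised at least 2-fold and 31.2% over 1394 genes lowered at least 2-fold. A mixture of LAMP2A and VT cells would keep the same share of every change if neither responded to DM-αKG. Of those raised genes 18.4% lay within 5 percentage points of Lamp2, and 15.6% of the 925 raised at least 8-fold. This argues against a mixture of cells that did not respond, although the window was not set against the noise of single genes. A mixture that also responded to DM-αKG would spread the shares, so for it the values decide nothing. Libraries of the same VT cultures under another label are argued against by Lamp2 itself, at a log2 fold change of 0.74 (SE 0.035) above VT, with 95.4 to 99.3 CPM in single libraries against 56.9 to 60.0. VT cells of another culture were not tested, since the labels do not say how the libraries of a group relate. A lower expression of Lamp2 in the treated cells (log2 fold change -2.06), which might come from loss of the introduced gene, selection or the treatment, cannot be told apart from an action of DM-αKG downstream of LAMP2A, because treatment and Lamp2 level change together and no group received DM-αKG without LAMP2A.

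Fibroblast and feeder cell genes were high in LAMP2A, although the cultures were feeder-free per the labels. Of 17 fibroblast and feeder cell genes tested, 4 had 5 CPM or more in VT and 0 were in another list, and the most abundant in LAMP2A were Tagln (1404 CPM), Vim (1016 CPM), Acta2 (486 CPM) and Col5a1 (156 CPM), with Col1a1 at 59.2 CPM. Cells of another type mixed with unchanged ES cells would lower all naive pluripotency genes alike if they expressed none of them. The log2 fold changes of these genes had an SD of 0.66 over 17 genes against a median SE of 0.036. From 6.58% of the VT level was left for Tcl1 to 57.3% for Tbx3. This argues against cells without naive gene expression as the whole cause. Cells that express some of the naive genes would also give unequal falls, so for them the spread decides nothing. Whether some cells changed fully or every cell changed in part cannot be told apart, since the median of 23.2% of the VT level left is a sum over cells.

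Targets of hypoxia-inducible factor stood above VT in LAMP2A+DM-αKG, where the median of the naive pluripotency list was -0.32 and that of the hypoxia list 1.07. In LAMP2A without DM-αKG 10 of the 20 were above VT too, among them P4ha2 and Ddit4. Scaling between libraries moves all genes alike, whereas the list median lay 1.07 (log2) above that of all other tested genes (SD 0.76 over members). Camera had already compared the list with the other genes, so this gap is no separate support. Prolyl hydroxylases that mark hypoxia-inducible factor for degradation use 2-oxoglutarate, and whether this bears on the rise was not tested. Culture density or oxygen in the treated dishes cannot be told apart from an effect of DM-αKG by the list median of 1.07, because no VT cells received DM-αKG and each group may have been grown in its own dishes.

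Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. In edgeR the real split was the 1 of 10 with as many genes: 12355 for LAMP2A against VT, 12081 for LAMP2A+DM-αKG against LAMP2A and 8517 for LAMP2A+DM-αKG against VT, where the highest of the other splits gave 0 in each. At an unadjusted p under 0.05 the highest other split gave 55, 39 and 494 genes, against 12420, 12177 and 9069 for the real ones. Each other split puts libraries of both groups on each side, so differences between the groups add to its spread. Low counts in the other splits follow from this, and no conclusion about chance is drawn from them.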
